A study of Homo sapiens with 8 samples.

How the data were processed

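Total RNA, per the labels of A549 cells, was measured on 8 Agilent arrays, 4 labelled control and 4 labelled circFOXO3 overexpression. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was prepared with a kit for circulating and exosomal RNA, and cRNA was labelled with Cy3 by a single-dye protocol. The deposited scanner files, however, hold 2 channels and name a 2-colour extraction protocol, per the file headers. What the red (Cy5) channel held is not given in the sources used here. The green (Cy3) channel was therefore analysed as planned for 1-colour arrays, and the red channel was used only as an alternative and for additional values.

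The scanner intensities were extracted with Agilent Feature Extraction 12.1.1.1, per the file headers, while the submitters' processing notes name Agilent Feature Extraction 12.0.3.1. The processed green intensity is background-subtracted and dye-normalized against the red channel within each array, per the file headers, so a dye effect can enter a green value. The deposited series table holds values on a log10 scale, which follow the spike-in pattern of the scanner files' log10 ratios of red over green (r of at least 0.996 over 10 spike-in probes). Its scale and centring were read from the values, the median of every column being 0, and whether its sign runs as red over green for the samples stays unknown. No column of it matched the scanner ratio of its own array (r from 0.0836 to 0.208), so it was used only as an alternative source.

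Processed green intensities were scaled by the array's 75th percentile on the log2 scale, so a value of 0 is that percentile. Since at most 46.4% of the spots of an array were well above background, the percentile was taken over the 18251 probes well above background on all 8 arrays. Values not above 0 took the array's lowest positive value. Control spots and spots marked as outliers by the extraction software were left out (46 to 90 non-control spots per array), saturated spots were kept (0 on each array), and spots of a probe were averaged on the log2 scale. A probe was tested if it was well above background on all 4 arrays of at least 1 group, and 4 such probes were dropped because every spot on an array was marked. This left 21121 probes. Probes were named through RefSeq accessions of assembly GRCh38.p14, without versions: 31104 of 58201 probes matched a gene symbol, and 1976 of the 33080 probes with a RefSeq accession did not. The array design used build hg19, so no coordinates are given. Each gene was represented by its tested probe of highest mean signal over the 8 arrays, which gave 12557 genes.

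Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, group as the only term), with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Log2 fold changes are circFOXO3 minus control. Gene lists with at least 3 tested members were tested with camera (preset correlation 0.01), beside camera with estimated correlation and fry. The text was to name, in each direction, the 12 genes with the largest log2 fold change among those past the threshold whose groups did not overlap, or, with fewer than 5 passing, the 5 genes of smallest p as not passing. FOXO3 was always named, and each passing list and each list fixed for circFOXO3, FOXO3 or microRNAs was described with its 2 to 4 members of smallest p. The comparison, the lists, the naming rule and most alternatives were fixed before the data were examined. Exact permutation tests over all assignments of 4 and 4 arrays were two-sided, with a smallest p of 0.0286. Although the series describes independent experiments, near-identical signals on some arrays mean that p-values measure only the spread between these arrays, which may be partly technical.

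The fit was tested on simulated data for this comparison with 21121 probes, 200 of them changed. With an SD of 0.2 per probe, 100% of 2-fold changes were recovered, with 9 false calls. With the SD that each probe showed within the groups, 0% of 2-fold changes and 78% of 8-fold changes (3 on the log2 scale) were recovered, the latter with 14 false calls. In a simulation of 20 lists of random probes with an SD of 0.2, camera called the 1 shifted list and 0 others. Every simulated probe was drawn independently, whereas members of real lists moved together (estimated correlation up to 0.827, for ribosomal proteins). The simulation therefore does not measure false list calls in these data. Simulated arrays were drawn independently too, unlike the near-identical arrays here. Recovery and false calls of probes in these data are therefore not measured either.

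Alternatives covered scaling, background correction, the filter, the spread model, array weights, replicate numbers as a block, leaving out each array, the series table, averaging a gene's probes, and the set test. The mean signal column planned for normexp (offset 50) was not in the files, and the median signal was used. Slide or scan could not be used as a block, since all arrays shared 1 slide and 1 scan. Chosen after seeing the data were the percentile over all probes, green signal without dye normalization, the red channel, the red over green ratio, averaging of arrays of a group that correlated above 0.99, and leaving out the 3 arrays in doubt. Figures were drawn with matplotlib 3.10.9.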

Results

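RNA labelled as from A549 cells, a human lung adenocarcinoma line, was measured on 8 Agilent gene expression arrays. Labels place 4 arrays in a control group and 4 in a group overexpressing circFOXO3, a circular RNA formed from an exon of FOXO3, which encodes a forkhead transcription factor. The series describes each group as 4 independent experiments and names microRNA expression as the readout, whereas the arrays carried probes for messenger and long noncoding RNA. The question was which transcripts differ when circFOXO3 is overexpressed. Each array held 60901 non-control spots, which carried 58201 distinct probes. Between 41.1% (circFOXO3 array 4) and 46.4% (circFOXO3 array 3) of the non-control spots were well above background. The control arrays 1 to 4 had 45.5%, 45.2%, 45.3% and 42.6%, and the circFOXO3 arrays 1 and 2 had 43.0% and 42.2%. With 4 arrays per group, the number of arrays limits the precision of every value.

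The arrays did not group by label. Over the 18251 probes well above background on all 8 arrays, the arrays labelled control 1, 2 and 3 correlated with each other at r = 0.998, with an SD of the log2 difference between 0.14 and 0.15. The array labelled control 4 correlated with control 1, 2 and 3 at r = 0.886 to 0.887, with an SD of 1.17, and 28.0% to 28.3% of probes differed at least 2-fold. The same array correlated with circFOXO3 1 and circFOXO3 2 at r = 0.997, and only 11 and 15 probes differed at least 2-fold from it on those arrays. The arrays circFOXO3 3 and circFOXO3 4 correlated with each other at r = 0.920 and with every other array at no more than 0.923. These correlations are across probes, which are not independent replicates. In a comparison of spots, control 1 and control 2 were closest: over 260 probes with at least 10 spots, 3.85% differed at an unadjusted p under 0.05, against 5% by chance. Control 2 and 3 gave 12.3%, and control 1 and 3 gave 13.1%. Matching spots by position, which is more sensitive, gave 9.23% for control 1 and 2, with 2 probes past the adjusted threshold. That matching put 19 probes past it for control 2 and 3, and 12 for control 1 and 3. Repeated hybridizations of one RNA can differ in this way too, so whether these arrays are separate replicates stays unknown. They were kept separate as labelled, and their average was tried as an alternative. In the comparison of spots without matching by position, control 4 gave 26.2% with circFOXO3 1 and 18.8% with circFOXO3 2. For these pairs 21 and 12 probes passed the adjusted threshold. Between circFOXO3 1 and 2 it was 7.69%, with 0 probes past it. With control 1, 2 and 3, control 4 gave 93.8% to 95%. Because a control array matched arrays of the other label, directions are given for arrays as labelled.

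**Figure D1:**
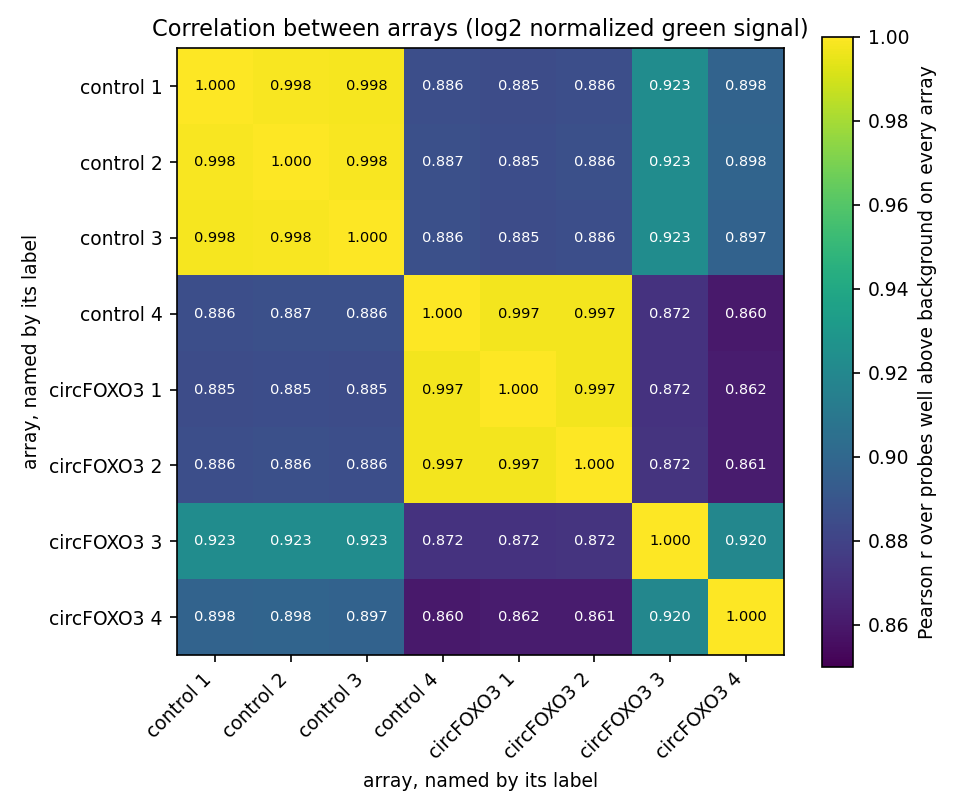
Pearson correlation of normalized log2 green signals between each pair of the 8 arrays, over the 18251 probes well above background on every array, with arrays on both axes and r as colour and number. The array labelled control 4 correlates at 0.997 with circFOXO3 1 and 2 and at 0.886 to 0.887 with the other controls.

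FOXO3 was measured by 3 probes, all designed on its linear messenger RNA, and whether any of them lies in the exon that forms the circle was not determined. A probe outside that exon checks nothing about overexpression of the circle. On the representative probe, the normalized log2 signal was -0.67, -0.72 and -0.61 on the arrays labelled control 1, 2 and 3 but 1.18 on control 4. The arrays labelled circFOXO3 1 to 4 had 1.07, 1.25, 0.65 and 1.05. The control mean was -0.20 ± 0.92 (SD, n = 4) and the circFOXO3 arrays had an SD of 0.25 (n = 4), with a log2 fold change of 1.21 with an SE of 0.44, or 2.31-fold. It did not pass the threshold (limma adjusted p = 0.362; two-sided exact permutation p = 0.114, against a smallest possible 0.0286), and control 4 lay above 3 of the 4 circFOXO3 arrays. Another probe gave a log2 fold change of 1.23 with an exact permutation p of 0.143. The dimmest of the 3 probes separated the groups, with control 4 at -3.52 and the lowest circFOXO3 array at -3.46. It gave a log2 fold change of 0.85 with an SE of 0.26 and an exact permutation p of 0.0286, the smallest the design allows. Exact permutation p-values take the arrays as exchangeable, which near-identical arrays are not, so those given here are no valid measure of chance. Among all genes, 6.71% were separated by label in the same way on their representative probe. Without control 4, which leaves near-identical controls counted as separate replicates, the representative log2 fold change was 1.67 and passed the threshold (limma adjusted p = 0.00563). With near-identical arrays of a group averaged it was 0.695 (adjusted p = 1).

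**Figure D2:**
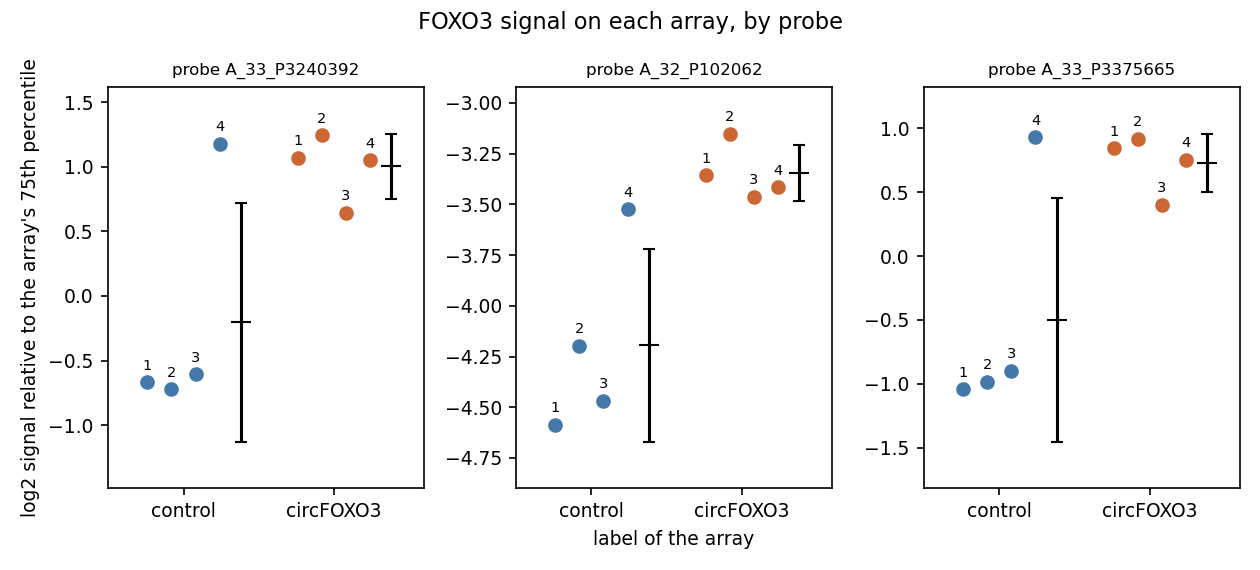
FOXO3 signal on each array for each of its 3 probes: normalized log2 green signal on the vertical axis, arrays by label on the horizontal axis, and black bars for the group mean and SD (n = 4). On the probe at the left, the array labelled control 4 is at 1.18, and the other controls lie between -0.72 and -0.61.

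No probe passed the test for a difference between the labels. Of 21121 probes tested with limma, 0 had an adjusted p under 0.05, so 0 were higher, 0 were lower and 0 differed at least 2-fold. The lowest adjusted p was 0.362. On independent simulated arrays with the SD each probe showed within the groups, 0% of 2-fold changes were recovered. The 0 calls therefore do not show that the labels do not differ. At an unadjusted p under 0.05 there were 2814 probes, 13.3% of those tested, 1578 higher and 1236 lower. Chance would give 1056 with independent arrays. Among 12557 genes, 843 (6.71%) had all 4 circFOXO3 arrays on one side of all 4 control arrays, against 2.86% for independent arrays. Near-identical arrays are not independent, so neither excess can be read as an effect of the label. With such arrays of a group averaged (2 control and 3 circFOXO3 values), 52 probes were at an unadjusted p under 0.05. Without control 4, limma called 2319 probes, 1445 higher and 874 lower. Without the 3 arrays in doubt (control 4, circFOXO3 1 and circFOXO3 2), it called 5561. Both fits count the near-identical control 1, 2 and 3 as separate replicates, so their calls may rest on too small a spread. With near-identical arrays of a group averaged, limma called 0. That fit keeps the profile of control 4 and circFOXO3 1 and 2 on both sides of the comparison. Its 52 probes at an unadjusted p under 0.05 were fewer than the 1056 of chance. It could hardly call a probe, so its 0 does not weigh against the other counts.

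The 5 genes with the smallest p in each direction are given as not passing, each at a limma adjusted p of 0.362. On the higher side stood NFIX, a nuclear factor I transcription factor, with a log2 signal of -5.61 ± 0.62 in control and -3.95 ± 0.53 in circFOXO3 (SD, n = 4), and a log2 fold change of 1.66. GBP2, an interferon-induced guanylate-binding protein, had a log2 fold change of 2.68 but was well above background on 1 of the 4 control arrays. RASA4B, of the Ras GTPase-activating proteins, had 1.83 and was well above background on 2 of the 4 controls. MROH1 had 2.11 and the zinc finger factor ZBTB7B 1.05. On the lower side, ALDH1A1, a retinaldehyde dehydrogenase abundant in A549 cells, was at 4.93, 4.90 and 4.98 on control 1, 2 and 3, at -4.61 on control 4, and at -5.35, -5.02, -8.68 and -8.22 on the circFOXO3 arrays. Only circFOXO3 1 and 2 of the circFOXO3 arrays had ALDH1A1 well above background, so its log2 fold change of -9.37 rests in part on arrays without a measured level. CPLX2, a regulator of synaptic vesicle release, and the noncoding RNA TARID were not well above background on any circFOXO3 array. Averaged over the 4 controls, their signals were at least 6.56-fold and 1.98-fold brighter. CPLX2 was at -2.77 to -2.63 on control 1, 2 and 3 but at -5.47 on control 4. TARID was at -5.10 to -4.68 on control 1, 2 and 3 and at -5.68 on control 4. On control 4 alone the bounds do not hold. These bounds set the control mean against, per dim array, the higher of the probe's own signal and the lowest signal called well above background. INTS2, an Integrator complex subunit, had a log2 fold change of -1.52 and was well above background on 1 of the 4 circFOXO3 arrays. WDR89 had -1.16. With normexp and percentile scaling TARID and INTS2 changed sign. Normexp also shrank the other differences: with quantile normalization the log2 fold change was 0.26 for RASA4B, 0.31 for NFIX, 0.67 for MROH1, 0.36 for ZBTB7B, 0.59 for GBP2, -0.40 for WDR89, -0.76 for CPLX2, -0.23 for INTS2 and -5.73 for ALDH1A1. With percentile scaling the 5 higher genes were at 0.58 to 0.96, WDR89 at -0.16, CPLX2 at -0.54 and ALDH1A1 at -5.49, so the bounds given for CPLX2 and TARID do not carry over to normexp. In every named gene, control 4 was the control nearest to the circFOXO3 arrays. Its gap to the remaining controls was smaller, against the spread of the controls, in TARID, NFIX and RASA4B than in the others.

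Of 35 gene lists fixed beforehand, 32 had at least 3 members tested, and 7 passed camera with its preset correlation. None of the 7 passed with the correlation estimated for each list, where every adjusted p of these 7 was 0.785, and none passed with fry, where the lowest adjusted p was 0.407. No member of any list passed limma's test adjusted over all probes. For each of the 7, the array labelled control 4 lay outside the range of control 1, 2 and 3.

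Genes of the G2 phase and mitosis were lower on the circFOXO3 arrays: 46 of 52 members had a lower value, with a median log2 fold change of -0.58 (camera adjusted p = 2.72e-07; adjusted p = 0.785 with an estimated correlation). KIF18A, a mitotic kinesin, had -1.71, TOP2A, the topoisomerase that separates sister chromatids, -1.70, and ECT2, a cytokinesis factor, -1.41. The list mean, as deviation from each gene's mean over the 8 arrays, was 0.45 to 0.47 on control 1, 2 and 3, -0.30 on control 4, and -0.33, -0.32, -0.02 and -0.41 on circFOXO3 1 to 4. Its median was -0.37 both with normexp and percentile scaling and with near-identical arrays averaged. Adjusted over the list alone, 0 members passed.

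Interferon response genes were higher, with a median log2 fold change of 1.31 over 26 members, 6 of them lower (camera adjusted p = 0.000538; adjusted p = 0.785 with an estimated correlation). IFI44, an interferon-induced protein, was at -9.05, -9.02 and -9.08 on control 1, 2 and 3, not well above background there, and at -2.83 on control 4, -2.83 and -2.72 on circFOXO3 1 and 2, and -0.76 and -0.58 on circFOXO3 3 and 4. ISG15, a ubiquitin-like modifier, had a log2 fold change of 3.12 and IFITM3, a restriction factor for virus entry, 2.86. The list mean was -1.22 to -1.16 on control 1, 2 and 3, 0.43 on control 4, and 0.43, 0.37, 0.57 and 1.75 on circFOXO3 1 to 4. Adjusted over the list alone, 0 members passed. The list did not pass without circFOXO3 4 (median 0.98, camera adjusted p = 0.0514) or with array weights (median 0.99, adjusted p = 0.446), within a range of 9.99e-07 to 0.785 over the alternatives. The median was 0.75 with normexp and quantile normalization and 2.09 without the 3 arrays in doubt.

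Targets of NRF2, the transcription factor of the oxidative stress response that is constitutively active in A549 cells, were lower in 20 of 22 members, with a median of -1.20 (camera adjusted p = 0.000348; adjusted p = 0.785 with an estimated correlation). PGD, an enzyme of the pentose phosphate pathway, had a log2 fold change of -1.72, the glutathione-conjugate transporter ABCC1 had -1.24 and the heme oxygenase HMOX1 had -1.80. The list mean was 1.24 to 1.26 on control 1, 2 and 3, -1.40 on control 4, -1.40 and -1.37 on circFOXO3 1 and 2, 0.87 on circFOXO3 3 and -0.45 on circFOXO3 4. With near-identical arrays of a group averaged, the median was -0.16 and the camera adjusted p 0.493, within a range of 5.46e-09 to 0.785 over the alternatives. The median was -1.96 without control 4 and -2.75 with array weights. Adjusted over the list alone, 0 members passed.

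Cytosolic ribosomal protein genes were higher in 53 of 58 members, with a median of 0.37 (camera adjusted p = 3.97e-05; adjusted p = 0.785 with an estimated correlation). RPS21 had a log2 fold change of 0.61 and RPS3A 0.65. The list did not pass after quantile normalization (median -0.02, camera adjusted p = 0.936), with normexp and quantile normalization (0.01, adjusted p = 0.732) or with near-identical arrays averaged (0.11, adjusted p = 0.186). Its adjusted p ranged from 1.73e-10 to 0.936 over the alternatives, and its median was 0.72 with array weights. The list mean was -0.36 to -0.30 on control 1, 2 and 3, 0.31 on control 4, and 0.46, 0.45, -0.33 and 0.11 on circFOXO3 1 to 4. Hypoxia and glycolysis genes had a median of 0.91 over 30 members (camera adjusted p = 0.00891; adjusted p = 0.785 with an estimated correlation). Among them the glucose transporter SLC2A1 had 1.24, and hexokinase HK2 was at -4.87, -4.91 and -4.53 on control 1, 2 and 3 but at 1.80 on control 4. The hypoxia list mean was -0.78 to -0.77 on control 1, 2 and 3, 0.48 on control 4, and 0.49, 0.50, -0.48 and 1.34 on circFOXO3 1 to 4. Without circFOXO3 4 the hypoxia median was 0.50 and did not pass (camera adjusted p = 0.35), and without control 4 it was 1.39. The median was 0.55 with normexp and quantile normalization and with near-identical arrays averaged, and 1.37 in the authors' value table. The list also did not pass without the filter, with normexp and percentile scaling or with array weights, and its adjusted p ranged from 5.75e-14 to 0.785 over the alternatives. Heat shock genes had a median of -0.48 over 19 members (camera adjusted p = 0.00625; adjusted p = 0.785 with an estimated correlation). The chaperones HSPH1 and HSP90AA1 had -0.91 and -0.71, but the collagen chaperone SERPINH1 had 0.70. The heat shock list mean was 0.39 to 0.43 on control 1, 2 and 3, -0.22 on control 4, and -0.19, -0.23, 0.14 and -0.72 on circFOXO3 1 to 4. With near-identical arrays averaged the heat shock median was -0.25 and did not pass (camera adjusted p = 0.182, within a range of 9.45e-05 to 0.785 over the alternatives). Genes of drug export and drug resistance had a median of -0.73 over 13 members (camera adjusted p = 0.038; adjusted p = 0.785 with an estimated correlation). In that list 2 members, ALDH1A1 and TOP2A, passed adjusted over the list alone (adjusted p = 0.0311), and neither exports drugs. The list mean was 0.90 on control 1, 2 and 3, -0.20 on control 4, and -0.28, -0.22, -0.60 and -1.39 on circFOXO3 1 to 4. Without circFOXO3 4 the median of that list was -0.26 (camera adjusted p = 0.17), and without control 4 it was -0.93 (0.0604), so neither passed. The list also did not pass with the stricter filter, array weights, median scaling, no scaling or the percentile over all probes, and its adjusted p ranged from 0.000258 to 0.785 over the alternatives. Its median was -0.42 and -0.39 with normexp, and -1.25 without the filter. In the ribosomal, hypoxia and heat shock lists, 0 members passed adjusted over the list alone.

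**Figure D3:**
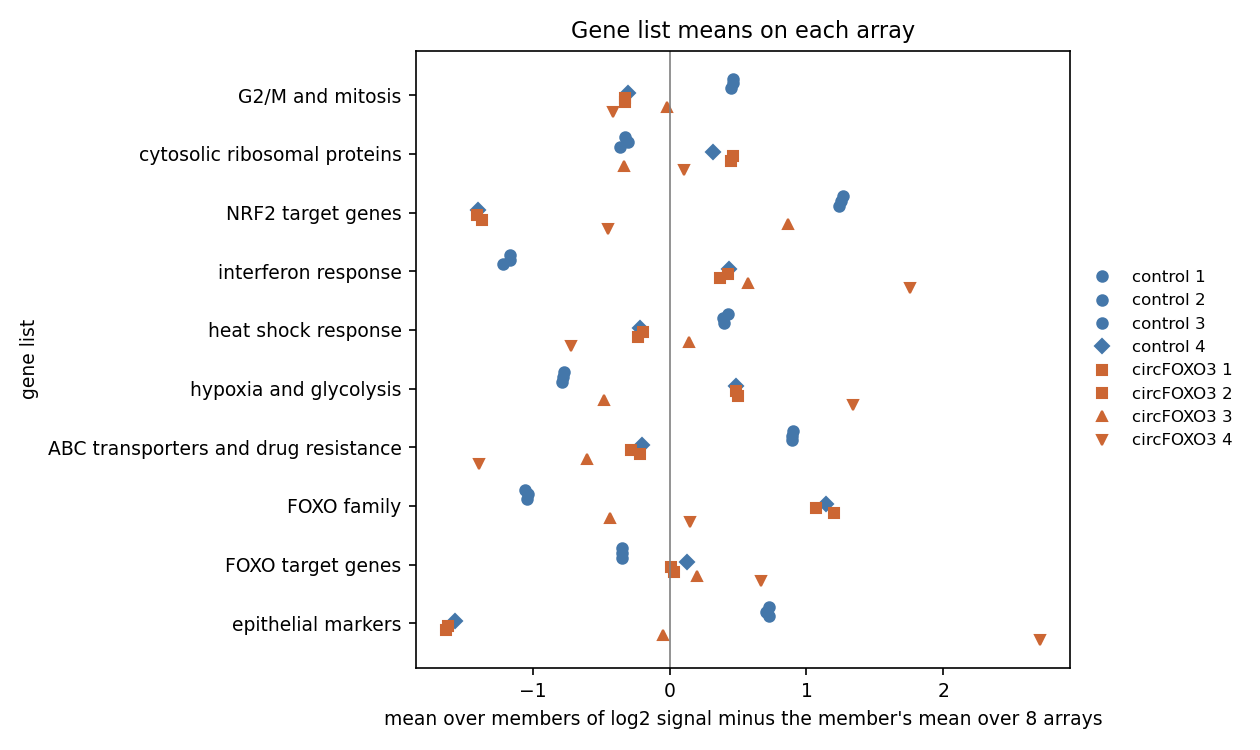
Mean over the tested members of 10 gene lists on each array: the horizontal axis is the log2 signal minus each member's mean over the 8 arrays, and points are arrays by label. The NRF2 list is at 1.24 to 1.26 on control 1, 2 and 3 and at -1.40 on the array labelled control 4.

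FOXO genes and the lists fixed for circFOXO3 and microRNAs did not pass camera. The FOXO family had a median log2 fold change of 1.19 over 4 members (camera adjusted p = 0.131). FOXO3 and FOXO6, which had 1.59, passed limma adjusted over the list alone (adjusted p = 0.0497 for both). FOXO6 was at -3.35, -3.31 and -3.49 on control 1, 2 and 3. On control 4 it was at -0.99, within the circFOXO3 range of -1.91 to -0.83. FOXO4 had 1.17 and was well above background on 2 of the 4 controls, and FOXO1 had 0.01. Without control 4 the family had a median of 1.79 and passed camera (adjusted p = 0.0343, the lowest of its alternatives, which reached 0.785). Its median was 0.39 with near-identical arrays averaged (adjusted p = 0.478), 0.55 and 0.76 with normexp, 0.35 in the authors' value table and 2.09 with array weights. FOXO target genes had a median of 0.33 over 32 members (camera adjusted p = 0.298). They passed with near-identical arrays averaged (median 0.29, adjusted p = 0.0319) and in the authors' value table, whose direction is unknown (median 0.18, adjusted p = 0.0342), within a range of 0.0319 to 0.881 over the alternatives. Their median was 0.20 without circFOXO3 4 and 0.002 with array weights, and 0.63 without the 3 arrays in doubt. Of these, the growth arrest gene GADD45A had 1.41, CITED2 had 1.75, and PRDX3, a mitochondrial peroxiredoxin, had -0.89. TXNIP, an inhibitor of thioredoxin, had 5.44 and was well above background on 1 of the 4 controls, control 4. Proteins reported to bind circFOXO3 had a median of -0.24 over 8 members (camera adjusted p = 0.525), with CDKN1A at 0.30 and CDK2 at -0.32. The median of that list was -0.36 without circFOXO3 4 and -0.11 without circFOXO3 3, and its sign changed with normexp and percentile scaling and with near-identical arrays averaged. MicroRNA host genes had a median of 0.07 over 12 members and camera pointed lower (adjusted p = 0.881). MIR503HG had -2.04 and MIR23AHG 0.70. The imprinted MEG3 had -2.51 and was not well above background on circFOXO3 4. H19 was at 0.28 on control 4, 0.27 on circFOXO3 1 and 2 and -1.76 to -1.75 on control 1, 2 and 3, and was not well above background on circFOXO3 3 and 4. The median of that list was negative after quantile normalization, with normexp and quantile normalization, with near-identical arrays averaged, without scaling, and without circFOXO3 3 or circFOXO3 4. Without control 4 it was 0.006. Genes of microRNA processing had a median of 0.15 over 17 members (adjusted p = 0.963), but 0.004 without circFOXO3 2, 0.04 without circFOXO3 1, 0.06 without circFOXO3 3 and 0.06 without control 2, and negative with near-identical arrays averaged and without the 3 arrays in doubt. In that list the silencing factor TNRC6A had -0.66 and the Argonautes AGO4 and AGO1 had 0.92 and 0.32. Genes of circular RNA formation and turnover had a median of -0.06 over 16 members (adjusted p = 0.614), with the RNA helicase UPF1 at 0.71 and the splicing factor SRSF1 at -0.85. The median of that list ran from -0.20 without circFOXO3 1 to 0.12 without circFOXO3 4, and was positive without circFOXO3 3 and with array weights. From the list of microRNAs reported for circFOXO3 and their host genes, 2 members were measured, too few for a test: CARMN at 0.21 (well above background on 3 of the 4 circFOXO3 arrays) and MIR22HG at -0.11. In the lists of FOXO targets, circFOXO3 partners, microRNA hosts, microRNA processing and circular RNA genes, 0 members passed adjusted over the list alone.

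The remaining 19 lists had camera adjusted p from 0.0628 (housekeeping references) to 0.963. Markers of other cell types were among them: leukocyte genes at 0.377, fibroblast and stroma genes at 0.963, and blood plasma, platelet and erythroid genes at 0.963. In the fibroblast list TAGLN passed adjusted over the list alone (adjusted p = 0.0246). Epithelial markers (adjusted p = 0.58) were measured in 12 members with a median of -0.79. Their list mean was 0.71 to 0.73 on control 1, 2 and 3 and -1.57 on control 4. On circFOXO3 1 to 4 it was -1.62, -1.63, -0.05 and 2.71. The median and the camera direction differed in sign in 3 lists, and the mean and the camera direction in 2. All arrays came from 1 slide and 1 scan, with controls in one row of the slide and circFOXO3 arrays in the other, so that row and label cannot be told apart.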

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

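Apart from the counts of splits, the tests in this part were chosen after the results were seen. Camera with an estimated correlation had been planned, but its use here to weigh an explanation was chosen afterwards. Within each group of 4 arrays, 42 sets of values were examined for an array far from the other 3, and 18 had one. Chance would give about 2 in independent sets. These sets are not independent, and most were picked for a small p in the same data, so that number is no valid reference. In 17 of the 18 the array was control 4, which restates that it stood apart from the near-identical control 1 to 3. The measure is the gap to the nearest array over the whole range of the group. For FOXO3, control 4 gave 0.938 on the representative probe and 0.927 on another. Among the named genes it gave 0.992 for ALDH1A1, 0.951 for CPLX2, 0.947 for WDR89, 0.897 for INTS2, 0.867 for GBP2, 0.859 for MROH1 and 0.853 for ZBTB7B. Among list means it gave 0.998 for drug resistance, 0.993 for hypoxia and glycolysis, 0.9899 for NRF2 targets, 0.981 for G2 and mitosis, 0.967 for the interferon response, 0.944 for heat shock and 0.911 for ribosomal proteins. For the share of spots well above background it gave 0.908. The remaining case was circFOXO3 4, whose interferon mean gave 0.853.

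The first pattern is that the array labelled control 4 matched circFOXO3 1 and 2 and stood apart from control 1 to 3. Signal level and within-array normalization are argued against: over the 4563 brightest probes, on signals without dye normalization, its mean r was 0.998 with circFOXO3 1 and 2 and 0.760 with control 1 to 3, a difference of 0.237. An effect of circFOXO3 overexpression as the whole cause is argued against, since circFOXO3 1 and 2 correlated less with circFOXO3 3 and 4 (r = 0.861 to 0.872) than with control 1 to 3 (0.885 to 0.886), a difference of mean r of -0.01885, while an effect within these differences stays open. RNA of more than one cell source under one label is a candidate explanation: pairs of one label with r under 0.99 were discordant in a median of 11 of 39 HOX genes, whose on and off states are kept by a cell lineage, and 11 of 1000 sets of other genes of like mean signal reached as many (median 7), although HOX genes are regulated together and such sets are not. Whether a label, a file or a culture is at fault cannot be read from these values. No circFOXO3 array was near-identical to control 1 to 3. Since circFOXO3 3 and 4 share a label at r = 0.920, this does not exclude a swap. The closest array, circFOXO3 3 (r at most 0.923), was discordant with each of control 1 to 3 in 3 of 39 HOX genes.

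Between the labels limma called 0 probes (2814 at an unadjusted p under 0.05), and since any of the 35 splits of the arrays into 4 and 4 calls at least 0, the number of splits with as many (35) says nothing about chance. Another split, control 1, 2 and 3 with circFOXO3 3 against the rest, called 4925 probes, the highest, and 2 splits called any, which points to a structure of the samples. The second pattern, 7 lists past camera, was matched by 27 of the 35 splits, with 15 lists in the highest of the others, so chance cannot be excluded. With the correlation of list members estimated, 0 of the 7 passed, which is consistent with list members moving together across arrays. Biological differences between the labels stay open and untested for the lists.

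The third pattern is that the authors' value table did not match the scanner ratios. Another processing of the same arrays is argued against: the highest correlation in size between any column and any scanner ratio, level or difference between arrays was 0.313, while ratios recomputed without normalization correlated with the scanner ratios at 0.978 or more. Rows in another order are argued against too, since spots of one probe scattered in the table with at most 0.126 of the SD over all repeated spots. That the table holds other hybridizations stays open. No biological explanation was tested.

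In the red over green ratios, which the comparison did not use, the representative FOXO3 probe was above the highest control (0.35 on the log2 scale) on circFOXO3 1 at 0.735 and on circFOXO3 3 at 0.668. Its ratios on circFOXO3 2 and 4 were -0.08 and 0.348. The dimmest FOXO3 probe was above its highest control (0.286) on circFOXO3 1 at 0.524 but not on circFOXO3 3, at -0.0808. The other probe had 0.837 and 0.730 on those arrays against a highest control of 0.444.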

How the results depend on the processing

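The counts of probes stayed at 0 in 22 of 25 alternatives. Array weights, which gave control 4, circFOXO3 3 and circFOXO3 4 weights of 0.0547, 0.0452 and 0.0359, called 17753 probes, 11222 higher, 6531 lower and 6825 at least 2-fold, with FOXO3 at 1.83. The weights leave the test to control 1 to 3 and circFOXO3 1 and 2, which are near-identical within each label and differ between labels. Leaving out each array in turn gave 0 to 2319 probes, 0 to 1445 higher, 0 to 874 lower and 0 to 1806 at least 2-fold, all counts above 0 without control 4. FOXO3 then ran from 1.035 to 1.668, passing only without control 4, and the cause was not tested. Without the 3 arrays in doubt, 5561 probes were called, 2619 higher, 2942 lower and 3566 at least 2-fold, with FOXO3 at 1.513. That alternative was chosen after seeing the data, like the red channel, the ratio, the averaging and the added scalings. As without control 4, the near-identical control 1 to 3 count as separate replicates there, so the counts may rest on too small a spread. FOXO3 was higher in 24 alternatives, from 0.695 to 1.83. These include the red channel (1.342), and since what it held is not given, its direction between conditions is unknown. The value for FOXO3 was 0.116 in the red over green ratio and 0.339 in the authors' value table, whose directions are unknown too. The count of lists was 5 to 10 except with an estimated correlation and with fry, both 0, and 5 to 8 when arrays were left out.

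With the replicate numbers as a replicate block, 0 probes passed (2323 at an unadjusted p under 0.05), FOXO3 was 1.207 and 7 lists passed. The deviations of same-numbered arrays correlated at -0.644, -0.647, 0.556 and -0.453, and 1 of the 4 controls correlated best with its own number. Because the controls other than control 4 were near-identical, the deviations of the controls mainly set control 4 against the rest. These correlations therefore cannot decide whether the numbers pair the arrays. The block changed no call.

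Signs were opposite as follows, and the cause was not tested. In the authors' value table, where the unknown direction leaves open which signs changed: RASA4B -0.2586, NFIX -0.5803, MROH1 -0.117, ZBTB7B -0.3969, CPLX2 0.1051, ALDH1A1 0.3533, and the medians of drug resistance 0.01024, ribosomal proteins -0.03437, G2 and mitosis 0.1982, heat shock 0.1408, interferon -0.2318, NRF2 targets 0.2888, circFOXO3 partners 0.06075, microRNA hosts -0.1255 and microRNA processing -0.1459. Of the lists with an opposite sign in that table, interferon and NRF2 targets passed camera there (adjusted p = 0.0342 for both). With normexp and percentile scaling, which moved the median of all probes from 0.06 to 0.24: TARID 0.1413, INTS2 0.08853 and circFOXO3 partners 0.01165. Ribosomal proteins were -0.01763 after quantile normalization. MicroRNA hosts were -0.05082 after quantile normalization, -0.06162 without scaling, -0.01291 with normexp and quantile normalization, and -0.1557 with near-identical arrays averaged. The circular RNA list was 0.2984 with array weights. With near-identical arrays averaged, circFOXO3 partners were 0.04412 and microRNA processing -0.02997, the latter -0.01243 without the 3 arrays in doubt. When arrays were left out, microRNA hosts ran from -0.04168 to 0.08577 and the circular RNA list from -0.1998 to 0.1213. Without that table, 192 of 224 values for named genes and 265 of 312 for lists kept their direction and side of the threshold, and 2 and 14 changed sign. A further 30 values of named genes passed, 31 list calls were lost, 14 of them with an estimated correlation or fry, and 2 were gained. Slide or scan as a block was not run, since there was 1 of each. At most 46.4% of the spots of an array were well above background, which limits dim genes such as TARID.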

Other observations

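The tests and the genes named in this part were chosen after the values were seen. Among the lists fixed beforehand, the members with the widest range over the 8 arrays differed between arrays of one label. KRT18 and KRT19, keratins of simple epithelia, were at 6.08 to 6.22 and 3.15 to 3.16 on the arrays labelled control 1, 2 and 3, and at -0.62 and -3.57 on control 4. They were at -0.58 and -3.77 on circFOXO3 1, -0.77 and -4.13 on circFOXO3 2, 3.72 and 4.97 on circFOXO3 3, and 5.55 and 6.71 on circFOXO3 4. The tight junction gene CLDN4 was at 3.39 and 5.21 on circFOXO3 3 and 4 and at -2.43 to -2.14 on the 4 controls, -2.04 on circFOXO3 1 and -2.003 on circFOXO3 2. SPARC, a matrix-binding protein, was at 1.38 on control 4 and 1.41 and 1.43 on circFOXO3 1 and 2. On control 1, 2 and 3 it was at -2.70, -2.86 and -2.84, and it was not well above background on circFOXO3 3 and 4. SNAI2, a repressor of epithelial genes, was not well above background on control 1, 2 and 3 but was at 0.05 on control 4. The imprinted noncoding RNA H19 was at 0.28 on control 4 and 0.27 on circFOXO3 1 and 2, at -1.76, -1.76 and -1.75 on control 1, 2 and 3, and not well above background on circFOXO3 3 and 4. MEG3, also imprinted and noncoding, was at 0.61 to 0.71 on control 1, 2 and 3, at -3.47 on control 4, and not well above background on circFOXO3 4.

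Of 39 HOX genes, 25 were well above background on each of control 1, 2 and 3, 30 on control 4, 28 and 30 on circFOXO3 1 and 2, 24 on circFOXO3 3 and 16 on circFOXO3 4. HOXA11 was well above background only on control 4 (-0.56), circFOXO3 1 (-0.50) and circFOXO3 2 (-0.52). HOXB13 was at 2.06, 2.08 and 2.10 on those arrays, at -1.46 to -1.37 on control 1, 2 and 3, and not well above background on circFOXO3 4. In pairs of one label with r under 0.99, a median of 28.2% of HOX genes was discordant, against 12.4% of all genes on the array.

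The red channel followed the green channel on each array (r = 0.972 to 0.993 across probes), with genes that departed. Among probes well above background in green, 2.50% (circFOXO3 3) to 9.73% (circFOXO3 4) differed at least 2-fold between the channels. Log2 ratios of red over green correlated across probes at 0.794 to 0.842 between control 1, 2 and 3, and at 0.449 between circFOXO3 3 and 4. Control 4 correlated at 0.501 with circFOXO3 2 but at 0.190 with circFOXO3 1, and the latter 2 arrays correlated with each other at 0.322. On control 1, 2 and 3, CEACAM6, a cell adhesion molecule, had ratios of -6.90, -4.48 and -6.96. GPC6, a glypican, was well above background in green on those 3 arrays and in red on none of them. On circFOXO3 4, SERPINB4 and SERPINB3, serine protease inhibitors, had ratios of 3.95 and 3.86, and IDO1, an interferon-induced tryptophan-degrading enzyme, had 3.67. TXNIP had a ratio of 3.04 on control 4, 0.76 on circFOXO3 1 and 1.78 on circFOXO3 2. What the red channel held is not given, so these values carry no direction between conditions.

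In the authors' value table, whose sign is unknown, the columns for control 1 and circFOXO3 3 correlated at 0.775 and those for circFOXO3 2 and circFOXO3 4 at 0.735 across probes, and all other pairs at 0.345 or less. HMOX1 was among the most extreme genes in both of the first pair, at 5.08 and 4.88 on the log2 scale.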
